A study of Mus musculus with 6 samples.

How the data were processed

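RNA sequencing of mouse liver was compared between 3 libraries from livers given an adeno-associated virus (AAV) that carries green fluorescent protein and 3 libraries from livers given an AAV that carries Ly6d. Per the labels, RNA integrity was assessed on a Bioanalyzer and libraries followed standard Illumina protocols. Bowtie 0.12.2 and the mm10 build are named in the submitters' processing notes, without their role or order. The read counter, its strand setting, the annotation and the normalisation tool are not given in the sources used here.

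The deposited values are normalised read counts, handled here as a signal that is never negative, for 1834 genes in 6 libraries. Within each deposited column every value was a whole multiple of a single step (100% of values within 0.001 of a whole number of steps), and the step did not depend on the gene. This is the form that reads take when the authors divide them by a size factor per library. One read was worth 0.968, 1.08 and 0.844 in the AAV-GFP libraries and 0.972, 0.997 and 1.09 in the AAV-Ly6d libraries. The step of AAV-Ly6d replicate 2 lies near 1, so an automatic test for recovered reads did not apply to that column, although only 6.00% of its values were whole numbers. Reads recovered for it enter the count tests, which are added alternatives, the look at how the table was chosen, and the sums and numbers of reads given here, but not the limma fits. The recovered reads of the 1834 genes summed to 3248078, 3442460 and 3448888 in AAV-GFP and to 4359932, 3990935 and 3835101 in AAV-Ly6d. These sums cover part of each library, and the full depth is not known.

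The 1834 genes were chosen by a rule that is not given in the sources used here. The deposited order of the genes followed the p-value of a DESeq2 fit to the recovered reads (Spearman's rho 0.987 across genes, which are not independent replicates). In that fit 1544 genes had an unadjusted p under 0.05, the largest p was 0.0911, and the smallest absolute log2 ratio of group means was 0.32. The table was therefore treated as genes chosen for a difference between these same libraries, and adjusted p-values inside it understate the error. A simulation of 20000 genes, of which 1000 changed 2-fold, showed the size of this for an assumed mixture. When the 1767 genes with p under 0.05 were kept and adjusted among themselves, 46.3% of the 1519 calls were unchanged genes. With the adjustment over all simulated genes this share was 2.12% of 424 calls.

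Gene identifiers were matched to the GENCODE mouse annotation, release M21, on GRCm38, which is the mm10 assembly, and 1833 of 1834 had a symbol. Coordinates, the length of the longest annotated transcript and its GC content come from that annotation. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2(value + 1), without covariates. The 1780 genes with a value of at least 1 in at least 3 libraries were tested and 54 were not. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, and "rose" or "fell" refers to this call. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The test was tried on simulated data for 1834 genes with a dispersion of 0.05, where it recovered 65% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold, and called 8 of 1634 unchanged genes. Single values were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

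Before the data were examined, 47 lists of pathway genes and cell type markers (1048 genes) were fixed, together with the tests and the rule for named genes. That rule names Ly6d. It also names the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap and whose mean value reached the median of the tested genes (209). Unnamed gene models were left out. The rule further names the 4 members with the smallest p in each list with at least 5 tested members. Of the list genes, 220 are among the 1834, and 25 lists had at least 5 tested members. Because the table was chosen on these libraries, camera was not run, as the plan foresaw, and fry was not run either. Lists are given as counts of members that rose, fell or did not pass, over all tested genes and adjusted over the list alone.

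The alternatives fixed beforehand were a replicate block, each library left out in turn, other filters and pseudocounts, a rescaling by the median ratio, a fit without the trend and stricter thresholds. Alternatives added after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, and an adjustment over all 55450 annotated genes with those outside the table counted as not different. Fisher's exact test of the direction of a list's members against the other tested genes was also added, with Benjamini-Hochberg adjustment over 25 lists, as was a comparison of each list with 10000 random lists of tested genes matched on transcript length class. Both set a list against other genes of the same chosen table and treat genes as independent, so they describe the list inside the table only, and the percentages of matched lists, over 27 lists, are not adjusted. A list of glucocorticoid-induced liver genes and a list of BMP-SMAD target genes were written after some of their values had been seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.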

Results

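Liver RNA was profiled in mice on the same diet that received an AAV vector, a virus used to carry a gene into liver cells, with either green fluorescent protein (AAV-GFP, 3 libraries) or Ly6d (AAV-Ly6d, 3 libraries). Ly6d is a small membrane-anchored protein of the Ly6 family. The study title places the comparison in metabolic dysfunction-associated steatotic liver disease, and the question was how Ly6d overexpression alters liver gene expression. The deposited normalised read counts cover 1834 genes, which held between 3248078 and 4359932 reads per library. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

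Ly6d itself was far higher in the livers that received its vector. The gene lies on the minus strand of chromosome 15 from 74762056 to 74763620 (GRCm38). Its normalised read count was 56.1, 9.68 and 182 in the AAV-GFP libraries and 3181, 1799 and 3275 in the AAV-Ly6d libraries. The means were 82.7 ± 89.3 and 2751 ± 826 (SD, n = 3 each), a ratio of 33.3. The lowest AAV-Ly6d library held 9.87 times the highest AAV-GFP library. In limma, Ly6d rose by a log2 fold change of 5.79 (SE 0.88, adjusted p = 0.0182). The exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. The adjusted p of Ly6d in limma was 0.0867 without AAV-Ly6d replicate 1 and 0.0564 without AAV-Ly6d replicate 3, with log2 fold changes of 5.66 and 5.63.

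Across the table, endothelial, stellate and matrix genes were lower in AAV-Ly6d, whereas male-biased genes, amino acid catabolism, heat shock genes and interferon-stimulated genes were mostly higher. Of 1780 tested genes, 782 passed limma's adjusted p of 0.05, 283 that rose and 499 that fell. The groups did not overlap for 767 of the 782, and for 1504 (84.5%) of all 1780 tested genes. The genes of the table had been chosen for a difference between these libraries, so these counts hold inside the table only. Counts of list members likewise cover only members in the table. Tested were 10 of 17 listed endothelial, 8 of 17 stellate, 14 of 41 matrix and 20 of 33 male-biased genes. For amino acid, heat shock, interferon, complement and ribosomal genes they were 18 of 39, 6 of 13, 9 of 43, 8 of 42 and 19 of 42. Such counts are therefore not shares of a whole pathway. With the adjustment over all 55450 annotated genes, DESeq2 on the recovered reads called 117 genes, 42 higher and 75 lower, all among the 782, and limma called Moxd1 alone. The 117 held 8 endothelial, 3 stellate, 6 male-biased and 3 amino acid list members. They held 0 members of the matrix, heat shock, interferon, complement, ribosomal, periportal and endoplasmic reticulum stress lists.

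The split between rises and falls among the called genes depended on the scaling. It was 36.2% higher on the deposited scale and 69.2% of 941 calls after rescaling each library by the median ratio over the table, which moved the median log2 fold change by 0.34, from -0.67 to -0.33. With edgeR and TMM factors computed over the table, 72.5% of 823 calls were higher. Of the tested genes 0 changed direction after rescaling by the median ratio, so what changed was which genes passed the threshold. Median ratio and TMM factors take most genes as unchanged, which a table chosen for a difference need not meet. Fold changes here are on the deposited scale. The number of calls depended on which library was left out. Limma called 134 genes without AAV-GFP replicate 1, 139 without AAV-GFP replicate 3, 104 without AAV-Ly6d replicate 2 and 19 without AAV-Ly6d replicate 3. Without AAV-Ly6d replicate 1 it called 0, with 773 genes at an unadjusted p under 0.05. The median log2 fold change of the tested genes moved little in these 5 fits, from -0.67 to between -0.74 and -0.64, and was -0.40 without AAV-GFP replicate 2. Moxd1 is absent from the test when an AAV-Ly6d library is left out, since it then has fewer than 3 libraries with a value. AAV-GFP replicate 2 lay apart from the other libraries on the first principal component (-49.9, against -15.4 and -18.1 for the other AAV-GFP libraries), and 607 genes were called without it, 501 of them among the 782.

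Among called genes with a mean value of at least 209, the median of the tested genes, and no overlap between groups, the largest rises were those of Moxd1, a monooxygenase-like protein, of major urinary protein genes and of Ly6d. Moxd1 (chromosome 10, 24223517 to 24302790) had 0 reads in the AAV-GFP libraries and a mean of 642 ± 117 (SD, n = 3) in AAV-Ly6d, at least 673-fold higher against a floor of 3 reads over the group. The major urinary protein genes Mup15, Mup7 and Mup13 rose by log2 fold changes of 6.58, 4.22 and 3.83, and the pseudogene Mup-ps19 by 3.12. Their sequences are nearly identical and can share reads, so the values of single copies are uncertain, as is that of Serpina1e (log2 fold change 3.18, adjusted p = 0.0134 in limma), one of several near copies of the alpha-1-antitrypsin gene. Tff3, a secreted trefoil factor, rose by 4.17 and held 481 ± 419 in AAV-Ly6d against 20.4 ± 4.98 in AAV-GFP (SD, n = 3). Smaller rises were seen for Nab2, a corepressor of EGR transcription factors (2.46), Selenbp2, a selenium-binding protein with a near copy (2.41), the metallothionein Mt1 (2.31) and the hormone gene Fgf21 (2.28). Of the 12 rises, 9 passed without AAV-GFP replicate 1, 11 without AAV-GFP replicate 2, 10 without AAV-GFP replicate 3, 7 without AAV-Ly6d replicate 2, 3 without AAV-Ly6d replicate 3 and 0 without AAV-Ly6d replicate 1. The log2 fold changes of Mup7 and Fgf21 were 2.33 and 1.40 without AAV-GFP replicate 2, and that of Mt1 was 1.52 without AAV-GFP replicate 1. Mup7 did not pass in edgeR with TMM factors (3.12, adjusted p = 0.0503). No gene of this paragraph except Moxd1 has an adjusted p over the whole annotation below 0.05 in limma, but all except Mup7, Mt1 and Fgf21 passed it in DESeq2.

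Cyp2b9, a cytochrome P450 gene with female-biased expression and close relatives in the Cyp2b cluster, fell most. It lies on chromosome 7 from 26173411 to 26210661 and held 842 ± 1017 in AAV-GFP and 2.06 ± 1.79 in AAV-Ly6d (SD, n = 3), where the group had 6 reads in all. Its log2 fold change in limma was -7.63 (SE 0.91, adjusted p = 0.0134). Among the genes at or above that level, Vwf, the von Willebrand factor gene of endothelium, came next (-2.15), while several genes of lower level fell more, such as Cyp2a22 (-2.83). Plxnc1, a semaphorin receptor (-2.00), F8, which encodes coagulation factor VIII (-1.99), and Kdr, the VEGF receptor 2 gene (-1.88), fell by similar amounts. The receptor gene Calcrl (-1.81) and the endothelial phosphatase gene Ptprb (-1.80) fell as well. Amotl1 (-1.92), the scaffold gene Shank2 (-1.89), the water channel gene Aqp8 (-1.89), Serpina7, which encodes thyroxine-binding globulin (-1.86), and Slc17a4 (-1.79) also fell. All except Aqp8 passed the adjustment over the whole annotation in DESeq2. Of the 12 falls, 10 passed limma without AAV-Ly6d replicate 2, 7 without AAV-Ly6d replicate 3, 11 without AAV-GFP replicate 3 and 0 without AAV-Ly6d replicate 1.

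**Figure D1:**
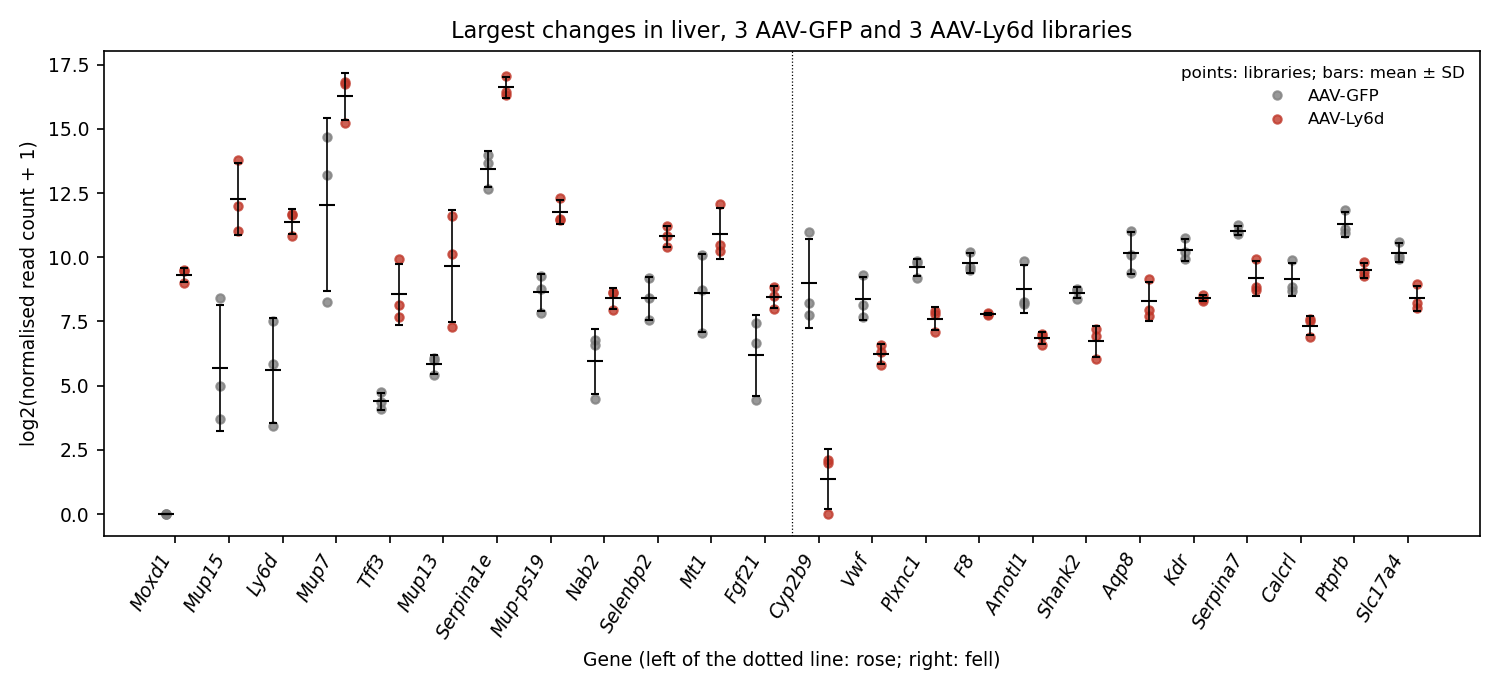
Normalised read count of the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 209 and no overlap between groups, as log2(value + 1) on the vertical axis, for 3 AAV-GFP libraries (grey) and 3 AAV-Ly6d libraries (red); points are libraries and bars are mean ± SD. Called genes of lower mean, some with larger changes, are not shown.

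Markers of endothelial cells fell together. All 10 tested members of the endothelial list fell, over the tested genes and adjusted over the list alone, and 8 of them passed the annotation-wide adjustment in DESeq2. The median log2 fold change was -1.51. Stab2, a scavenger receptor of liver sinusoidal endothelium, fell by 1.30 on the log2 scale, and Fcgr2b fell by 1.37. Of 17 listed stellate cell and fibroblast markers 8 were tested. Of these 5 fell (6 adjusted over the list alone) and 3 did not pass, with a median of -1.45. Hgf, the hepatocyte growth factor gene (-1.72), Lrat, a retinoid storage enzyme (-1.75), and Reln (-1.54) were among those that fell. Among 5 erythroid markers 2 fell, 3 did not pass and the median was -1.17; the globin genes among them share reads between copies, and 1 or 0 members passed without any one library; the median was -0.60 without AAV-GFP replicate 2, where 0 passed, and 12.4% of length-matched lists had a median as low. In the hepatocyte list 2 of 9 genes rose, Hnf4a (0.65, or 0.99 after rescaling) and Apoa1 (1.12), and 0 adjusted over the list alone. Without AAV-GFP replicate 2 the count was 3 and Apoa1 had a log2 fold change of 0.69, and without any one of the other libraries the count was 0. Of length-matched lists, 36.8% had a median as high as the hepatocyte list. The endothelial markers have long transcripts, with a median of 6090 bases against 3622 for the tested genes, and long transcripts were lower in AAV-Ly6d across the table. Of 10000 random lists of tested genes matched on transcript length, 0.44% had a median as low as the endothelial list and 1.65% as low as the stellate list. As few genes higher were seen in 11.1% and 3.72% of lists in the same order. The shared direction alone therefore did not set the endothelial markers apart from genes of their length. These comparisons were added after seeing the data. Endothelial and stellate members past the threshold were 10 and 4 without AAV-GFP replicate 2, 2 and 0 without AAV-Ly6d replicate 3, and 0 and 0 without AAV-Ly6d replicate 1. Stellate members numbered 3 without AAV-GFP replicate 1 and 3 without AAV-GFP replicate 3.

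Genes of the extracellular matrix fell with these markers. Of 14 tested members 9 fell (10 adjusted over the list alone), 5 did not pass and 0 rose. Lox, whose product cross-links collagen (log2 fold change -2.03), the collagen gene Col3a1 (-1.48), the protease gene Mmp2 (-1.38) and the fibrillin gene Fbn1 (-1.32) fell. Their transcripts are also long, with a list median of 5045 bases, and 4.19% of 10000 length-matched lists had a median log2 fold change as low. As few genes higher were seen in 5.46% of these lists. The matrix members past the threshold were 5 without AAV-GFP replicate 2, 5 without AAV-Ly6d replicate 2, and 0 without any one of the other 4 libraries.

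Genes with male-biased expression in mouse liver were mostly higher, and female-biased genes went both ways. Of 20 tested male-biased genes 11 rose, 9 did not pass and 0 fell (13 rose and 1 fell adjusted over the list alone), and 9 of the 20 are major urinary protein genes that can share reads. Mup20 rose by a log2 fold change of 1.92 and Mup21 by 1.68, and Cyp7b1, an oxysterol hydroxylase, rose by 1.37. Of 6 female-biased genes 3 fell, Cyp2b9, the lipoprotein receptor gene Vldlr (-2.58) and the fatty acid transporter gene Cd36 (-1.34), 1 rose, Cyp4a10 (0.94), and 2 did not pass, with the same counts adjusted over the list alone. By Fisher's exact test over 25 lists the direction of the male-biased genes differed from the rest of the table (adjusted p = 2.81e-05) and that of the female-biased genes did not (adjusted p = 1). The male-biased transcripts are short, with a median of 1373 bases, and 0.37% of 10000 length-matched lists had as many as 18 of 20 genes higher. The male-biased members past the threshold were 6 without AAV-GFP replicate 1, 6 without AAV-GFP replicate 3, 7 without AAV-Ly6d replicate 2, 0 without AAV-Ly6d replicate 1 and 0 without AAV-Ly6d replicate 3. For the female-biased list the counts were 2 without AAV-GFP replicate 3, 0 without AAV-Ly6d replicate 1, 2 without AAV-Ly6d replicate 2 and 2 without AAV-Ly6d replicate 3, against 4 with all libraries.

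Amino acid catabolism and the urea cycle were higher in AAV-Ly6d. Of 18 tested members 14 rose (16 adjusted over the list alone), 4 did not pass and 0 fell, with a median log2 fold change of 0.77. Their transcripts are short, with a median of 1937 bases. Of 10000 length-matched lists 1.70% had a median as high and 0.01% had all 18 genes higher. The transaminase genes Got1 and Gpt2 rose by 1.01 and 0.86, Arg1, the arginase of the urea cycle, by 0.78, and Tdo2, which degrades tryptophan, by 0.71. Periportal hepatocyte markers, which share genes with this list, rose in 6 of 7 cases (7 adjusted over the list alone), among them Sds (1.11) and Asl (0.92). Of 16 listed pericentral markers 2 were tested and both were lower (2 fell adjusted over the list alone). Lgr5 fell (-1.21) and Cyp2c29 did not pass (-0.91), both named after their values were seen. In the gluconeogenesis and glycogen list 5 of 8 genes rose, 1 fell and 2 did not pass (5 rose and 2 fell adjusted over the list alone). Igfbp1, an insulin-repressed secreted protein gene, rose by 1.72 and Fbp1, a gluconeogenic phosphatase, by 0.69 (0.46 without AAV-GFP replicate 2 and 1.04 after rescaling). Of 10000 length-matched lists 11.3% had a median as high as the periportal list and 5.25% as high as the gluconeogenesis list. The amino acid members past the threshold were 2 without AAV-GFP replicate 1, 1 without AAV-GFP replicate 3, and 0 without any one of the AAV-Ly6d libraries. The periportal count was 4 without AAV-GFP replicate 2 and 1 or 0 without any one of the other libraries, and the gluconeogenesis count was likewise 1 or 0 without any one library other than AAV-GFP replicate 2.

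Lipid genes moved in both directions. In de novo lipogenesis 4 of 10 members fell, 1 rose and 5 did not pass, over the tested genes and adjusted over the list alone. Srebf1, the gene of a lipogenic transcription factor, fell (-1.06), as did the fatty acid synthase gene Fasn (-1.23) and the elongase gene Elovl6 (-0.92), while the desaturase gene Fads2 rose by 0.71. Elovl6 did not pass after rescaling by the median ratio (-0.57, adjusted p = 0.0729 in limma) or in edgeR with TMM factors (-0.63, adjusted p = 0.0685). The direction of these 10 genes did not differ from the rest of the table (Fisher's exact test, adjusted p = 0.437 over 25 lists). Of 36 listed fatty acid oxidation and ketogenesis genes 6 were tested, and 5 of these rose (6 adjusted over the list alone). Cyp4a31 rose by 1.47, and Cpt1a, which admits fatty acids to mitochondria, rose by 0.58 (0.93 after rescaling); the Cyp4a genes are close copies. In lipid uptake and storage 4 of 9 genes rose, 2 fell and 3 did not pass (6 rose and 2 fell adjusted over the list alone), with the lipid droplet gene Plin5 higher (0.84) and Vldlr and Cd36 lower. The glycolysis list had 2 rises, 1 fall and 2 genes that did not pass among 5 (3 rose and 2 fell adjusted over the list alone), with the pyruvate kinase gene Pklr at -1.44. Of 10000 length-matched lists 22.1% had a median as low as lipogenesis, and 8.12%, 1.21% and 24.7% one as high as fatty acid oxidation, lipid uptake and storage, and glycolysis. Without AAV-GFP replicate 2 the fatty acid oxidation count was 3 and the glycolysis count was 2. Without any one of the other libraries, the 4 lists of this paragraph had between 0 and 2 members past the threshold each.

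**Figure D2:**
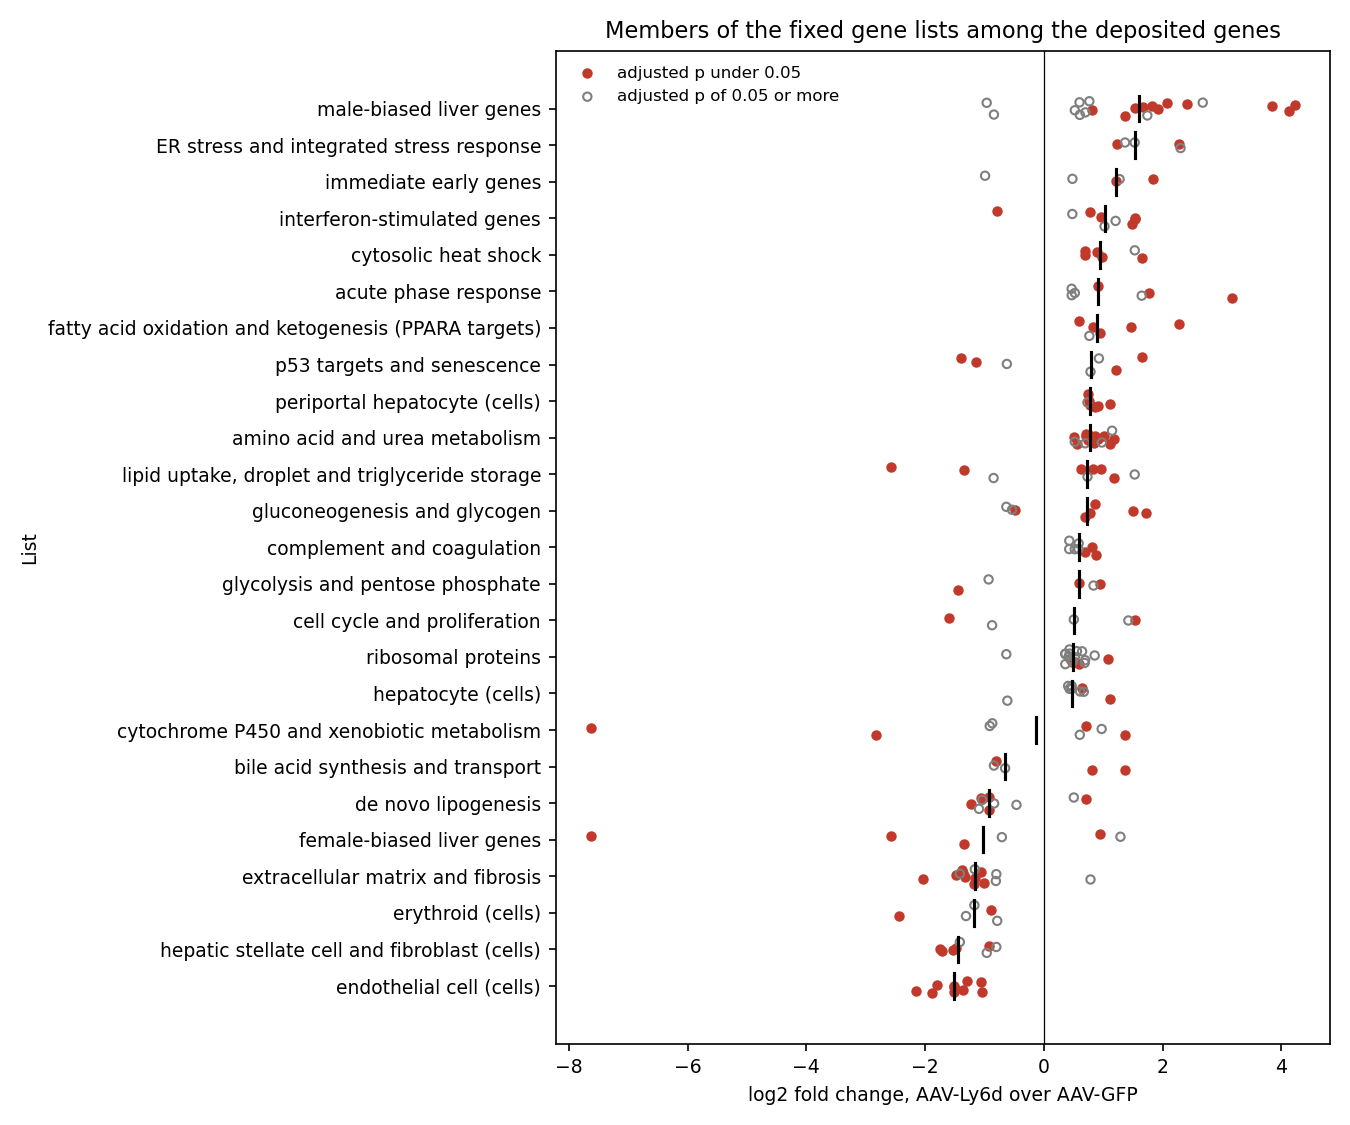
Log2 fold change (AAV-Ly6d over AAV-GFP, horizontal axis) of each tested member of the 25 gene lists with at least 5 tested members, listed on the vertical axis; filled points passed limma's adjusted p of 0.05, open points did not, and black bars are list medians. The medians run from -1.51 for endothelial markers to 1.61 for male-biased genes; that of the cytochrome P450 list (-0.13) turns positive when libraries are rescaled by the median ratio (0.21) and without AAV-Ly6d replicate 2 (0.11).

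In 5 lists of stress and immune response genes most members were higher, although complement and acute phase genes did not stand apart from length-matched lists by their medians. Of 6 cytosolic heat shock genes 5 rose (6 adjusted over the list alone), among them Hspb1 (1.65) and Hspa8 (0.89), which encode chaperones. Without AAV-GFP replicate 2 these were 1.03 and 0.59, and the list median was 0.60 in place of 0.94. Of 5 genes of endoplasmic reticulum stress and the integrated stress response 2 rose, Fgf21 and Trib3 (1.23), and 3 did not pass (3 rose adjusted over the list alone). Interferon-stimulated genes rose in 5 of 9 cases and fell in 1 (7 rose and 1 fell adjusted over the list alone). Oas1a, an antiviral enzyme with near copies, rose by 1.54 (1.00 without AAV-GFP replicate 2) and Irf7, an interferon regulatory factor gene, by 1.49. In the acute phase list 3 of 7 genes rose, Serpina1e, Hamp and Il1rn (4 adjusted over the list alone). Hamp, which encodes the iron hormone hepcidin, rose by 1.77. Of 8 complement and coagulation genes 3 rose, C8b (0.88), C6 (0.80) and F12 (0.69), and 5 did not pass (4 rose adjusted over the list alone). The log2 fold change of F12 was 0.44 without AAV-GFP replicate 2 and that of C6 was 0.53 without AAV-GFP replicate 3. Without any one library other than AAV-GFP replicate 2, these 5 lists had between 0 and 2 members past the threshold each. Of 10000 length-matched lists, 25.8% had a median as high as the complement list, 9.04% as high as acute phase, 1.63% as high as heat shock, 0.99% as high as the stress response list and 0.94% as high as the interferon list. As many genes higher were seen in 0.91%, 3.44%, 1.19%, 13.2% and 1.75% of lists in the same order. In the list of cytokines, chemokines and NF-kB targets both tested genes were lower (2 fell adjusted over the list alone). These were Il1a, which fell by 1.20 on the log2 scale, and Il1b, at -1.47, which did not pass, both named after their values were seen.

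Ribosomal protein genes were higher by small amounts. Of 19 tested members 18 had a positive log2 fold change, with a median of 0.49 (0.83 after rescaling), but 4 rose and 0 did adjusted over the list alone. Rpl38 rose by 1.09 and Rpl18 by 0.60 (0.94 after rescaling), and processed copies of these genes can share reads. Without AAV-GFP replicate 2 the members past the threshold were 9, 8 that rose and 1 that fell, and without any one of the other libraries 0 or 1. Their transcripts are short, with a median of 1120 bases. Of 10000 length-matched lists 61.0% had a median as high, but 0.10% had as many as 18 of 19 genes higher. Across the tested genes, 65.6% of the shortest and 11.7% of the longest of 4 equal classes by transcript length were higher in AAV-Ly6d. Spearman's rho between length and log2 fold change was -0.295 across 1779 genes, which are not independent replicates, and -0.331 without AAV-GFP replicate 2.

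**Figure D3:**
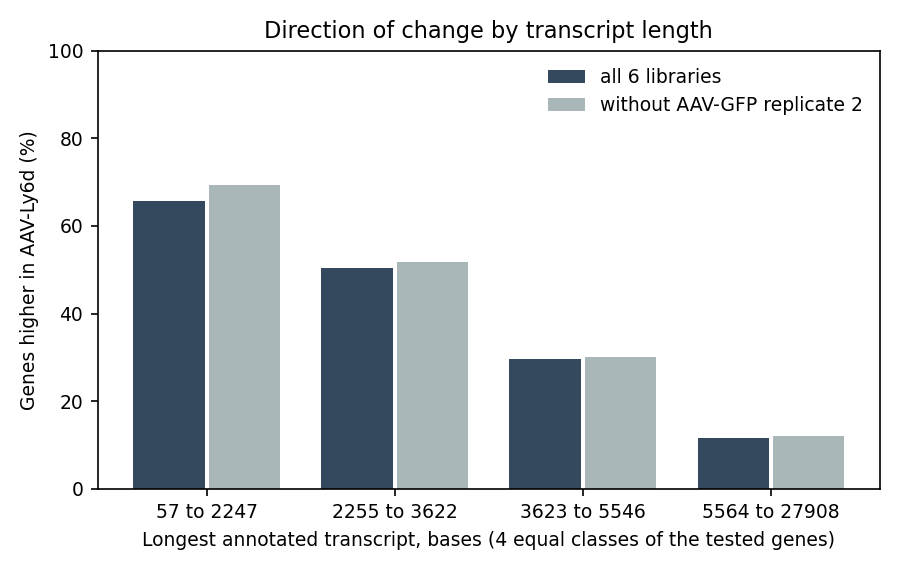
Percentage of tested genes that were higher in AAV-Ly6d (vertical axis) in 4 equal classes by the length of the longest annotated transcript in bases (horizontal axis), with all 6 libraries (dark) and without AAV-GFP replicate 2 (light). The percentage falls from 65.6 in the shortest class to 11.7 in the longest with all libraries, and starts at 69.4 without that library.

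Of the 47 lists, 8 had no member among the 1834 genes, and these were cholesterol synthesis, antigen presentation, Kupffer cells, neutrophils, dendritic cells, pancreas, skeletal muscle and sex chromosome genes. Since the table holds chosen genes, their levels were not analysed here.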

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

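The edgeR and DESeq2 fits, the adjustment over the annotation and the rescaled, edgeR and DESeq2 counts of list members were chosen after the results were seen. The count of 782 called genes stayed within 1.5 times under the other filters, pseudocounts, rescaling, the fit without the trend and the added fold threshold (531 to 941), under DESeq2 (1139) and under edgeR with TMM factors (823). It was 219 with edgeR and the deposited factors, 1 at an adjusted p under 0.01, and over all annotated genes 1 with limma and 117 with DESeq2; the last 2 follow from the larger number of genes adjusted for, and the cause for edgeR was not tested. Leaving out each library gave 0 to 607 genes; each of these fits has 5 libraries, so their number does not account for the range, and the cause was not tested. The 119 list genes past the threshold became 45 with edgeR and the deposited factors, and 0 to 107 with each library left out. Ly6d kept its direction in every fit, with log2 fold changes of 5.04 to 6.11 and adjusted p under 0.05 over the tested genes with all libraries, and 4.70 to 6.75 with each library left out, where 2 fits did not pass (adjusted p 0.0867 and 0.0564). Over all annotated genes its adjusted p was 0.567 in limma and 0.0016 in DESeq2. For the 108 other named genes, 1724 alternative fits gave 1161 with the same call, 533 that no longer passed, 30 that newly passed and 0 that reversed; the table holds no gene with an absolute log2 ratio of group means under 0.32, which leaves little room for a reversal.

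A replicate block gave 48 called genes, 20 list genes and a log2 fold change of 5.79 for Ly6d (adjusted p 0.0339). Same-numbered libraries did not deviate together (correlations -0.020, -0.047 and -0.058), so the numbers were not read as pairs. The alternatives for counts as the deposited unit (DESeq2 size factors in edgeR, and voom) and camera and fry were not run, because the table holds normalised values of chosen genes. The full depth is not known, and 216 of the 1834 genes had a mean under 10, where reads limit the precision.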

Other observations

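All tests in this part were chosen after the result they concern was seen, except the 3 tests on transcript length, whose bounds were set before their values were computed, and the lists fixed beforehand. Targets of bone morphogenetic protein signalling had values in the table. Of 7 tested members of a list written after the values of Hamp and Id1 had been seen, 6 rose and 1 fell, also adjusted over the list alone. Id1 rose by a log2 fold change of 1.88, Atoh8 by 1.15 and the feedback inhibitor gene Smad7 by 0.84, while Id4 fell by 1.40. Of 9 members whose values had not been seen, 5 were tested and 4 of these were higher (Fisher's exact test against the other tested genes, p = 0.0817). Of 10000 lists matched on transcript length, 9.82% had a median as high as the 7 members and 10.2% as many genes higher. The ligand gene Bmp2, which endothelial cells express in liver and which was chosen after its values were seen, fell by 1.47 on the log2 scale. The target list had 4 members past the threshold without AAV-GFP replicate 1, 2 without AAV-GFP replicate 3, 1 without AAV-Ly6d replicate 2, and 0 without AAV-Ly6d replicate 1 or 3.

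The other lists held smaller groups. In bile acid synthesis and transport 2 of 5 genes rose, Cyp7b1 and Cyp8b1 (0.82), and the export pump gene Abcb11 fell (-0.80), but did not pass after rescaling by the median ratio (-0.46, adjusted p = 0.130 in limma) or in edgeR with TMM factors (-0.54, adjusted p = 0.0887). In the cytochrome P450 list 2 of 8 rose, Por (1.36) and Sult1a1 (0.71), and 2 fell, Cyp2b9 and Cyp2a22 (-2.83). Among 5 cell cycle genes E2f8 rose (1.54, or 0.96 without AAV-GFP replicate 2, where it did not pass) and Cenpf fell (-1.60, or -1.47 in edgeR with TMM factors, where it did not pass). Among 7 p53 targets Bbc3 (1.66) and Btg2 (1.21) rose, and Eda2r (-1.40) and Trp53inp1 (-1.14) fell. Of 5 immediate early genes 2 rose, Junb (1.85) and Btg2. Adjusted over the list alone, the rises and falls were 2 and 1, 3 and 4, 1 and 1, 2 and 2, and 3 and 0 in the same order. Without any one library other than AAV-GFP replicate 2 these lists had between 0 and 2 members past the threshold each, and without that library the cell cycle list had 0 and the p53 list 2.

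AAV-GFP replicate 2 held 743167 normalised reads of Apob against 201516 and 186314 in the other AAV-GFP libraries and 187160 to 216089 in AAV-Ly6d. It also held 108679 of mt-Nd6 against 30678 and 32138. Both genes were chosen after their values were seen. The log2 fold change of Apob was -0.61 with all libraries and 0.03 without that library.

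The real split of the 6 libraries gave 782 called genes and the highest of the other splits 8, and 1 of the 10 splits gave as many as the real one. With 10 splits the smallest share is 0.1, and the table was chosen on the real split.

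Long transcripts were lower and short ones higher in AAV-Ly6d. The trend was still present among genes outside the fixed lists (rho -0.228) and given GC content (partial rho -0.261). This argues against the gene lists and GC content as its whole cause. It was also present without AAV-GFP replicate 2 (rho -0.331). That value cannot exclude this library as the cause, because the table was chosen with it included. Only 2 of 1738 genes changed direction without it. AAV-GFP replicate 2 differed from the other AAV-GFP libraries along the same axis, with rho 0.347 between length and its deviation from the group mean. A difference in RNA integrity or library preparation between the groups may give such a trend and stays open, because it would coincide with the groups and no integrity value per library was used here. An effect of Ly6d itself was not tested apart from it.

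Endothelial and stellate markers were lower in AAV-Ly6d. Of 10000 length-matched lists of the table's genes, 0.01% had a median below the -1.49 of the 18 markers, and the central 95% of lists ran from -1.19 to -0.55. This argues against transcript length as the whole cause of the size of the fall. The lists were drawn as if genes were independent and were not matched on expression level, so the share is not a p-value. The fall of these markers was also present without AAV-GFP replicate 2, with a median of -1.46, in a table chosen with that library included. Fewer endothelial cells in the pieces of liver may account for the endothelial markers, but this stays open. Their folds around a common -1.43 did not differ beyond their errors (Cochran's Q 13.8 over 10 markers, under its 95% bound of 16.9). This does not show that the folds were equal, and it cannot decide the question. Only 10 of 17 listed markers were in the table, which was chosen for a difference. Q also treats markers measured in the same libraries as independent. Lower expression per cell after Ly6d overexpression stays open as well.

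Male-biased genes were mostly higher in AAV-Ly6d. Female animals in the AAV-GFP group are argued against by Cyp4a12a, a male-specific gene named here after its values were seen. Its lowest AAV-GFP library held 0.340 of the AAV-Ly6d mean. This rests on 1 gene, and other male-biased genes varied. Mup7 held 307 in AAV-GFP replicate 2 against a mean of 88655 in AAV-Ly6d. Mup20 held 9999 in that library against a mean of 62887. Copies of these genes can share reads, so the question is not settled. Reads shared between major urinary protein copies would not raise the 11 other male-biased genes, of which 81.8% were higher (9 of 11). This argues against shared reads as the whole cause of the direction. The 39.3% of all tested genes that were higher is not a matched baseline, because transcripts of the male-biased list are short. In the shortest class by transcript length 65.6% were higher, and length-matched lists of 20 genes had a mean of 12.2 higher. Whether the 11 genes stand apart from genes of their length was not tested. A difference in growth hormone pattern, in strain or in age between the groups stays open and was not tested.

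Genes of amino acid catabolism were higher, and a candidate explanation is a glucocorticoid or fasting-like state of the AAV-Ly6d animals at sampling. Of 20 listed glucocorticoid-induced liver genes 12 were tested, and 3 of these, Sds, Tat and Tdo2, are also members of the amino acid list, so their rise restates the pattern; of the other 9, 5 rose (8 adjusted over these 9 alone) and 0 fell. Of 13 members whose values had not been seen when the list was written, 5 were tested, none of them in the amino acid list. Of these 5, 100% were higher (Fisher's exact test against the other tested genes, p = 0.00932). This p holds inside the chosen table only, treats genes as independent and is not matched on transcript length. But 2 of the 5 rose, Mt1 and Klf9 (0.54), and 3 did not pass, among them Mt2 (2.85). The restriction to these 5 was made after the whole list had been looked at. Feeding and handling at sampling are not given in the sources used here, and their part was not tested. Of the 9 genes outside the amino acid list, 4 passed the threshold without AAV-GFP replicate 2, 4 without AAV-GFP replicate 3, 0 without AAV-GFP replicate 1 and 0 without any one of the AAV-Ly6d libraries.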
